A study of Homo sapiens with 4 samples.

How the data were processed

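RNA from U87-MG glioblastoma cells was sequenced in 4 libraries, 2 with a control hairpin (shCON) and 2 with a hairpin against MAGED2 (shMAGED2), each assigned to its group and replicate number by its title. Libraries were prepared with the NEBNext Ultra RNA kit, per the labels' protocols. The deposited count table holds whole-number counts per gene and library, not normalised, and the authors used HISAT2, StringTie and SAMtools on hg38, per the submitters' processing notes, which name no role, version or option. The deposited FPKM table holds FPKM values, fragments relative to gene length and library total, computed by the authors with the same tools per the submitters' processing notes, with the gene lengths behind them not given. The annotation, the strand setting and the rules for reads that match several genes are not given in the sources used here, so that counts of overlapping genes, of antisense pairs and of near-identical copies are uncertain. The series design describes a stable knockdown of MAGED2, whereas the treatment protocol in the labels describes hairpins against ZDHHC15, transient transfection and harvest after 36 h. Which of these applies was not resolved, and both genes are reported.

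The table has 23444 gene entries, of which 19974 carry an Ensembl identifier, all found in GENCODE release 29, and 3470 are models without one that have no coordinates here. Of all entries, 4212 had 0 counts in every library. Coordinates are 1-based, from GENCODE 29 on hg38. All 4 columns of each table were mapped to a sample by the sample descriptions.

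Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr by group, library sizes were scaled by TMM (factors 1.020, 1.023, 0.945 and 1.014 for shCON 1 and 2 and shMAGED2 1 and 2), and a robust quasi-likelihood model with group as its only term was fitted to all 4 libraries. The test was two-sided, p-values were adjusted by Benjamini-Hochberg over 15293 genes, and the threshold was an adjusted p of 0.05. The biological coefficient of variation was 0.167, with 2 residual degrees of freedom and a median prior of 4.01. Standard errors were derived from the quasi-likelihood F statistic. Levels are given as CPM, counts relative to the library total scaled by TMM, with the SD over 2 libraries. Changes are log2 differences, shMAGED2 minus shCON. Total counts of 28673774 to 36234336 per library put the limit that a count of 0 allows (3 counts) at 0.083 to 0.105 CPM. Intervals (95%, exact conditional binomial) and these limits cover counting error only.

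Before the data were examined, 45 gene lists with 1108 symbols were written from textbook knowledge, of which 1104 matched the table, together with the design, the alternatives and the rule for naming genes. Lists were tested in limma 3.58.1 with camera at a preset correlation of 0.01, which gives the call, with camera at an estimated correlation and with fry, each adjusted by Benjamini-Hochberg over lists with at least 5 measured members. Camera at an estimated correlation also rests on the 2 residual degrees of freedom, so a call lost there cannot be laid to correlated genes alone. For each list the genes past the threshold are counted over all genes and again with p-values adjusted over the list alone. The rule named MAGED2, ZDHHC15, AKT1, AKT2, PIK3CA and further genes that are not reported here; the 8 genes with the highest and the 8 with the lowest change among those past the threshold, with a mean of at least 5 CPM and no overlap between the groups; the 4 per direction with the smallest p under the same conditions; and up to 4 members of each list with the smallest p. Other genes are said to be named after their values were seen. A further 7 lists were written after the data were examined and appear only among the closing observations.

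The alternatives set at the same time were DESeq2 size factors, upper-quartile factors or library size alone in the same edgeR test, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 2 libraries, no count filter, a filter of 5 CPM in 2 libraries, a model without robust estimation, a replicate block, and each library left out in turn. Changes on the log2(FPKM + pseudocount) scale understate those of low genes. Another 3 alternatives were added after seeing the data: mitochondrially encoded genes removed, each library's trend with GC content and length removed by loess (span 0.3), and annotated genes only. The tests were tried on simulated data drawn from the means and library sizes of these samples for 15293 genes with known changes. There edgeR made 136 calls, 22 of them false, with 0 in the wrong direction, and camera called the 1 list moved 1.5-fold and 0 others. Genes were drawn independently of each other there, and in the list simulation no gene outside the moved list was changed. The simulation therefore could not show false list calls that arise from correlated genes or from the many genes that change in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.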

Results

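RNA sequencing was carried out on U87-MG, an established human glioblastoma cell line, in 4 libraries. In 2 of them, named shMAGED2 here, the gene MAGED2 had been knocked down with a short hairpin RNA, and the other 2, named shCON, carried a negative control hairpin. MAGED2 is a member of the melanoma antigen (MAGE) family encoded on the X chromosome. The total counts over genes were 34235565 and 28673774 for shCON replicates 1 and 2, and 31160205 and 36234336 for shMAGED2 replicates 1 and 2. Between 17001 and 17312 genes had at least 1 count in a library. Nothing in the labels says that the replicates were grown as separate cultures, so p-values measure only the spread between these samples, which may be technical. The shCON pair differed by more than sampling noise (chi-square per degree of freedom 7.61), as did the shMAGED2 pair (95.65), and each library was counted as 1 replicate. The pairs across groups gave 146.45 to 237.93.

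MAGED2 (ENSG00000102316, a protein-coding gene on the plus strand of chromosome X, 54807599 to 54816012 in hg38) was the targeted gene and was low in both knockdown libraries. Its counts were 6090 and 5225 in shCON and 526 and 795 in shMAGED2. Scaled to library size, this was 176.3 ± 2.6 CPM (counts relative to the library total; SD, n = 2) against 19.8 ± 2.7 (SD, n = 2), so that 11.2% of the control level was left. The deposited FPKM values gave 80.3 ± 2.5 against 8.6 ± 1.6 (SD, n = 2), or 10.7% of control. MAGED2 fell by 3.16 on the log2 scale (SE 0.13; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000654). The treatment protocol in the labels names another hairpin target, ZDHHC15, a member of the palmitoyltransferase family. ZDHHC15 had 0 counts in all 4 libraries, which allows at most 0.088, 0.105, 0.096 and 0.083 CPM in shCON replicates 1 and 2 and shMAGED2 replicates 1 and 2 (limits from 3 counts, counting error only), so a change of it was not detectable at this depth. The series design, by contrast, describes stable knockdown of MAGED2, while that protocol describes transient transfection with harvest after 36 h.

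**Figure D1:**
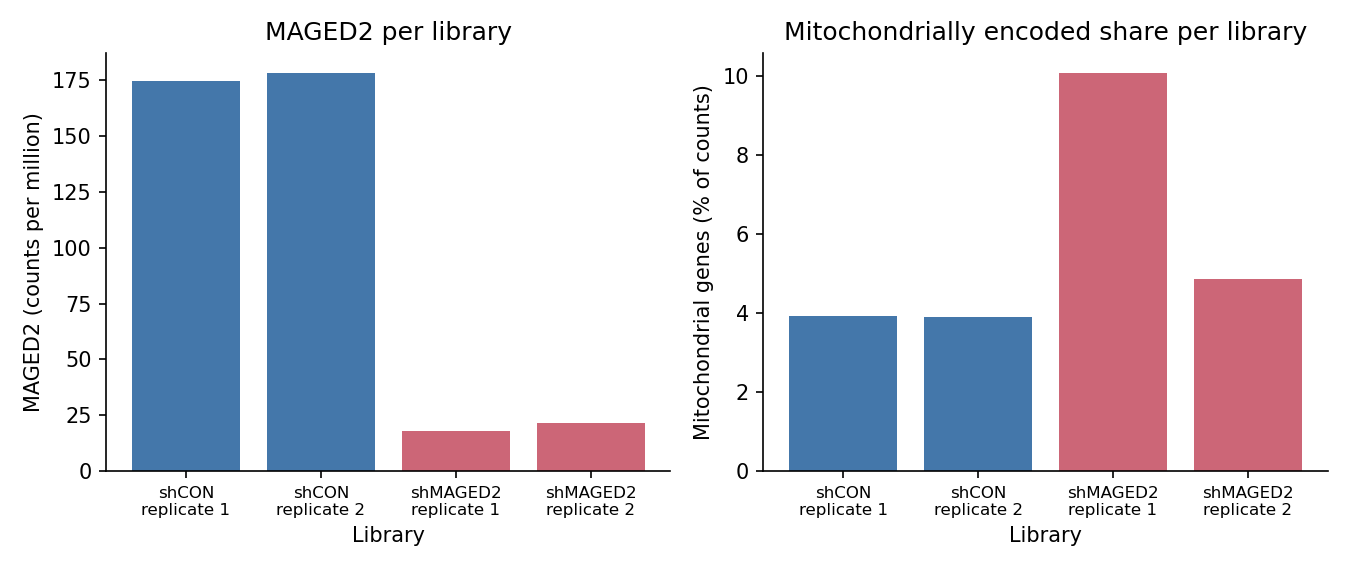
MAGED2 in CPM, the counts relative to the library total (left), and the share of all counts on mitochondrially encoded genes in percent (right), 1 bar per library, with shCON in blue and shMAGED2 in red. MAGED2 was at 174.5 and 178.2 in shCON and at 17.9 and 21.7 in shMAGED2, and the mitochondrial share of shMAGED2 replicate 1 (10.08%) lay above the 3.90% to 4.87% of the other 3 libraries.

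The comparison of shMAGED2 with shCON asked which transcripts change when MAGED2 is depleted. Of 15293 genes tested, 1874 rose and 1775 fell at an adjusted p under 0.05 (3649 genes, 23.9%), and 678 and 706 of these changed at least 2-fold. The rise with the smallest p was that of TXNIP, which encodes a thioredoxin-binding protein that restrains glucose uptake, from 35.2 ± 0.99 to 248 ± 25.4 CPM (log2 change 2.81, SE 0.12). RRM2, the small subunit of ribonucleotide reductase, rose from 92.2 ± 3.85 to 366 ± 17.2 CPM, and ID1, an inhibitor of basic helix-loop-helix transcription factors, from 15.0 ± 2.02 to 94.1 ± 3.59. A gene model without an annotation, newGene_4608, completed the 4 smallest p-values among rises, at 22.9 ± 0.46 against 149 ± 22.2 CPM. Among genes that fell, the smallest p belonged to GDF15, a stress-induced cytokine, from 278 ± 3.55 to 26.0 ± 0.53 CPM (log2 change −3.42, SE 0.10). The cytokines IL1B (159 ± 5.06 to 18.7 ± 0.62) and CXCL8 (452 ± 17.6 to 43.6 ± 6.36) and the endoplasmic reticulum chaperone HSPA5 (5542 ± 57.5 to 863 ± 58.8) followed (SD, n = 2 per group throughout). For these 8 genes the edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 0.000525 to 0.000739.

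The 8 largest rises among genes with a mean of at least 5 CPM were led by PLEKHA6 (log2 change 4.86, SE 0.27; chromosome 1, 204218851 to 204377665) and by the ephrin receptor EPHA2 (3.50, SE 0.26; chromosome 1, 16124337 to 16156087). The unannotated model newGene_6245 (3.37, SE 0.28), the endocytic adaptor STON2 (3.25, SE 0.23), the nicotinic receptor subunit CHRNA7 (3.17, SE 0.30), TXNIP, CHRFAM7A (2.72, SE 0.23) and newGene_4469 (2.71, SE 0.20) made up the rest. CHRFAM7A is a partial duplicate of CHRNA7, so the split of reads between them is uncertain. The 8 largest falls were those of AC245033.1, the retinol transporter STRA6 (−6.42, SE 0.42), the inducible heat shock gene HSPA6 (−5.91, SE 0.32), newGene_4864 (−5.40, SE 0.32), the receptor GPR1 (−4.57, SE 0.20), the netrin receptor UNC5B (−4.06, SE 0.18), KLHDC7B (−3.74, SE 0.28) and newGene_3437 (−3.74, SE 0.16). AC245033.1 had 734 counts over both shCON libraries and 1 count over both shMAGED2 libraries, a ratio of 756 with a 95% counting interval of 135 to 29900. It overlaps CPEB1 on the same strand, so its reads could be assigned to more than 1 gene. HSPA6 and its relatives of the HSP70 family, among them HSPA1B, have long near-identical stretches, which makes their values uncertain as well. RRM2, ALDOC, TAP2, TUBB3 and MT-ATP6, named here or further on, also overlap another coding gene on the same strand, and 35 of 165 annotated genes picked by the naming rule overlap one on the opposite strand only, where the strand setting of the counting is not given in the sources used here.

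An unadjusted p under 0.05 was found for 5806 genes, where 765 would be found by chance. Both shMAGED2 libraries lay on the same side of both shCON libraries for 66% of the tested genes (33.3% by chance). The number of genes changed was 1100 without shCON replicate 1, 1272 without shCON replicate 2, 6565 without shMAGED2 replicate 1 and 7447 without shMAGED2 replicate 2, fits in which the lone library is assumed to vary like the other group. Of 169 genes besides MAGED2 picked by the rule, some missed the threshold without shCON replicate 1 or 2. Among them were HK1, PFKP, FTH1, CDKN1A, MAGEL2 and the mitochondrially encoded genes. None of the picked genes that passed with all 4 libraries changed direction. AKT1, which did not pass, went from 0.014 to −0.005 without shCON replicate 1 and to −0.124 without shMAGED2 replicate 2. Counts of list members that pass depend on the library left out as well, and are given below for called lists where the larger of the 2 counts moves by over 1.5 times. MAGED2 passed in each of these fits, with changes of −3.03 to −3.31. In simulated counts the same test recovered 28.4% of 1.5-fold, 67.2% of 2-fold and 75.8% of 4-fold changes, and 22 of its 136 calls (16.2%) were false. Only 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold there, against 3649 genes called in the data. Since the adjustment depends on how many genes change, these shares need not hold for the data.

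**Figure D2:**
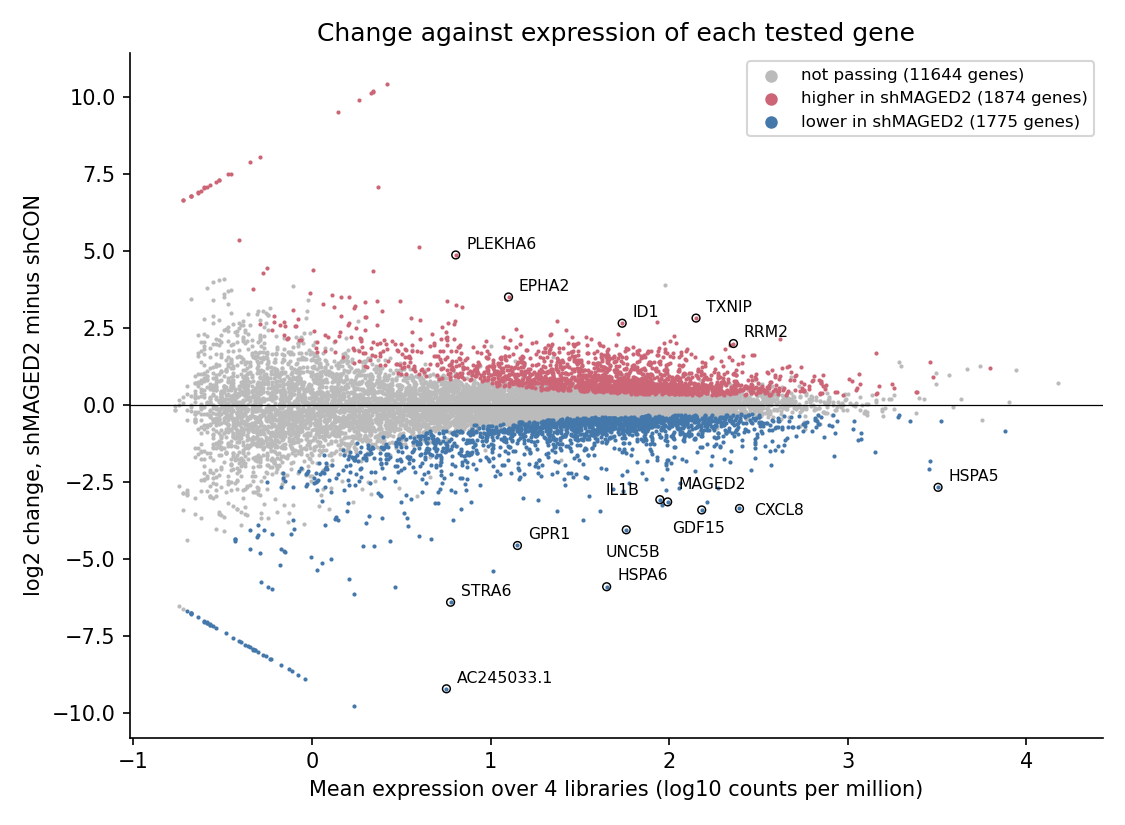
Log2 change (shMAGED2 minus shCON) against mean expression over 4 libraries (log10 CPM), 1 point per tested gene. The 1874 genes that rose are red, the 1775 that fell are blue, and circles mark named genes such as MAGED2 at −3.16 and TXNIP at 2.81. Straight lines of points at the left are genes with 0 counts in 1 group. The size of their plotted change is uncertain, since a ratio to 0 counts has only a lower limit.

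Genes of the unfolded protein response and of amino acid stress fell together. Of 22 measured genes of the unfolded protein response, which raises the folding capacity of the endoplasmic reticulum, 20 fell and 0 rose over all genes tested, and 21 fell when adjusted over the list alone. Their median log2 change was −1.32. Besides HSPA5 (−2.68, SE 0.10), they included HERPUD1, a factor of protein degradation at the endoplasmic reticulum (−2.72, SE 0.12), the co-chaperone DNAJB9 (−2.29, SE 0.11) and the chaperone HSP90B1, from 2127 ± 28.9 to 731 ± 14.7 CPM. Limma's camera gave a Benjamini-Hochberg adjusted p = 7.71e-36 with the preset correlation, and adjusted p = 0.11 with an estimated correlation. Among 31 targets of mTORC1 and ATF4, which supply amino acids and one-carbon units, 27 fell and 0 rose, and the counts adjusted over the list alone were equal. The median was −1.39, and GDF15, ALDH1L2 (−2.41, SE 0.11), asparagine synthetase ASNS (−2.21, SE 0.11) and the cystine transporter SLC7A11 (−3.26, SE 0.17) had the smallest p. Camera with Benjamini-Hochberg adjustment gave 9.06e-45 with the preset correlation, and adjusted p = 0.11 with an estimated correlation.

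Genes of the cell cycle rose in both shMAGED2 libraries. Of 41 genes of G2/M and mitosis, 40 rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 change of 1.62. KIF20A, a kinesin of cytokinesis, rose from 17.6 ± 1.33 to 85.6 ± 6.22 CPM, the mitotic kinase AURKA from 53.9 ± 2.12 to 178 ± 3.60, the cytokinesis scaffold ANLN from 91.0 ± 3.64 to 318 ± 24.2 and the cyclin CCNA2 from 44.5 ± 1.99 to 146 ± 4.40. Camera (preset correlation, Benjamini-Hochberg) gave an adjusted p = 1.89e-67, and adjusted p = 0.11 with an estimated correlation. Of 39 genes of G1/S and DNA replication, 36 rose and 0 fell, over all genes and adjusted over the list alone, and the median was 1.30. RRM2 (1.99, SE 0.10), thymidylate synthase TYMS (2.01, SE 0.11), the helicase subunit MCM4 (1.46, SE 0.09) and the transcription factor E2F2 (2.27, SE 0.14) had the smallest p. For this list camera gave a Benjamini-Hochberg adjusted p = 2e-45 with the preset correlation and adjusted p = 0.11 with an estimated correlation.

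Of 31 genes of MYC-driven ribosome biogenesis, 21 rose and 1 fell over all genes, and 24 rose and 1 fell when adjusted over the list alone (median 0.54); 7 rose without shCON replicate 1 and 8 without shCON replicate 2. The nucleolar proteins NOLC1 (1.12, SE 0.11) and FBL (0.95, SE 0.09), LYAR (1.33, SE 0.17) and BOP1 (0.94, SE 0.12) rose. The gene that fell was NOB1 (−0.36, SE 0.10), named after its value was seen. For this list camera gave, with Benjamini-Hochberg adjustment, p = 1.15e-07 with the preset correlation and adjusted p = 0.27 with an estimated correlation. Replication-dependent histone genes had few counts: of 15 measured, 4 rose and 0 fell over all genes, and 6 rose when adjusted over the list alone, with HIST1H1C from 3.29 ± 0.27 to 7.54 ± 1.35 CPM and HIST1H2BK from 8.45 ± 0.42 to 16.8 ± 3.85. This list was not called (camera, Benjamini-Hochberg adjusted p = 0.05 after rounding, just over the threshold), but was called in 8 of the alternative fits, among them limma-voom (0.0181), both FPKM fits (0.0364 and 0.0376), library size alone (0.0311) and without shCON replicate 1 (0.00644) or 2 (0.0477). Of 10 inhibitors of cyclin-dependent kinases and related brakes of the cycle, 3 rose and 3 fell, over all genes and adjusted over the list alone. CDKN3 (1.80, SE 0.16) and RBL1 (1.10, SE 0.10) rose, whereas BTG1 (−1.01, SE 0.11) and CDKN1A (−0.48, SE 0.09) fell, and camera with Benjamini-Hochberg adjustment gave 0.534.

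Genes of lipid synthesis fell. Of 24 genes of cholesterol synthesis and its regulation, 21 fell and 0 rose, over all genes and adjusted over the list alone, with a median of −1.06, and 13 fell without shCON replicate 1. DHCR7, which makes cholesterol in its last step, fell from 213 ± 0.77 to 73.0 ± 0.95 CPM, the sterol carrier STARD4 from 227 ± 3.79 to 51.2 ± 8.31, the SREBP-retaining protein INSIG1 from 570 ± 8.21 to 207 ± 13.6 and the oxidase MSMO1 from 182 ± 7.09 to 52.9 ± 6.06. Camera gave a Benjamini-Hochberg adjusted p = 2.24e-20 with the preset correlation, and adjusted p = 0.143 with an estimated correlation. Of 13 genes of fatty acid synthesis, 9 fell over all genes and 10 when adjusted over the list alone, and 0 rose (median −0.62). Without shCON replicate 1 or 2, 4 and 5 fell. The desaturase SCD fell from 4620 ± 30.5 to 1093 ± 38.3 CPM, FADS1 by 1.14 (SE 0.09), ACSL3 by 0.84 (SE 0.09) and ACSS2 by 0.97 (SE 0.10) on the log2 scale. The camera test gave a Benjamini-Hochberg adjusted p = 7.57e-07 with the preset correlation and adjusted p = 0.211 with an estimated correlation.

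Targets of the hypoxia factor HIF1 were also lower as a list: of 23 measured, 9 fell and 1 rose over all genes, and 11 fell and 3 rose when adjusted over the list alone (median −0.32). Without shCON replicate 1 or 2, 4 fell in each case, and 14 without shMAGED2 replicate 1. DDIT4, an inhibitor of mTORC1, fell from 196 ± 1.11 to 29.8 ± 11.3 CPM, and STC2 (−0.90, SE 0.10), MXI1 (−0.77, SE 0.10) and the peptide hormone ADM (−0.99, SE 0.15) fell. The mitophagy receptor BNIP3 rose (0.52, SE 0.13; named after its value was seen). With camera the hypoxia list had a Benjamini-Hochberg adjusted p = 0.0108 with the preset correlation and adjusted p = 0.302 with an estimated correlation, and the call ended in both fits to the FPKM values (0.0586 and 0.0849). Glycolytic enzymes, many of which HIF1 also drives, were mixed: 7 of 24 rose and 3 fell over all genes, and 8 rose and 3 fell when adjusted over the list alone. LDHA, which makes lactate, rose from 767 ± 8.73 to 1536 ± 117 CPM, HK1 by 0.79 (SE 0.09) and PFKP by 0.60 (SE 0.09), while ALDOC fell by 1.14 (SE 0.14) on the log2 scale. The glycolysis list was not called (camera, Benjamini-Hochberg adjusted p = 0.296), but was called without shMAGED2 replicate 1 (0.0137). Of 28 genes of NRF2 and oxidative stress defence, 12 fell and 3 rose over all genes, and 17 fell and 3 rose when adjusted over the list alone (median −0.37). Without shCON replicate 1, and likewise without shCON replicate 2, 7 fell, against 20 without shMAGED2 replicate 2. They included SLC7A11, GCLC (−1.36, SE 0.10), which limits glutathione synthesis, AKR1C1 (−2.55, SE 0.24) and ferritin heavy chain FTH1, from 9699 ± 118 to 5395 ± 329 CPM. MT2A (1.03, SE 0.14) and MT1X (1.75, SE 0.36), metallothioneins, and thioredoxin TXN (0.63, SE 0.13) rose, named after their values were seen. Camera on this list gave a Benjamini-Hochberg adjusted p = 5.66e-06 with the preset correlation and adjusted p = 0.195 with an estimated correlation.

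Inflammatory genes driven by NF-kB fell and interferon genes rose. Of 31 NF-kB genes, 17 fell and 2 rose over all genes, and 19 fell and 3 rose when adjusted over the list alone (median −0.95), with 10 lower without shCON replicate 1. IL1B (−3.08, SE 0.10), CXCL8 (−3.37, SE 0.13), the chemokine CXCL2 (−2.95, SE 0.14) and PTGS2, the inducible cyclooxygenase (−1.90, SE 0.10), had the smallest p. CSF1 (0.81, SE 0.11) and CCL5 (2.86, SE 0.68) rose and were named after their values were seen. The camera test gave a Benjamini-Hochberg adjusted p = 1.59e-11 with the preset correlation and adjusted p = 0.148 with an estimated correlation. Of 41 interferon-stimulated genes, 19 rose and 3 fell over all genes, and 20 rose and 4 fell when adjusted over the list alone (median 0.64), with 10 higher without shCON replicate 1 and 12 without shCON replicate 2. The antiviral effectors IFIT1 (13.3 ± 0.28 to 43.8 ± 0.98 CPM), OASL (21.2 ± 1.01 to 61.8 ± 4.10), IFIT2 (27.3 ± 1.96 to 72.6 ± 1.12) and IFIT3 (39.1 ± 0.36 to 90.1 ± 6.67) rose. STAT2 (−0.93, SE 0.10) and IRF1 (−0.93, SE 0.13), transcription factors of the response, and XAF1 (−1.74, SE 0.26) fell, named after their values were seen. For interferon genes camera gave a Benjamini-Hochberg adjusted p = 1.54e-05 with the preset correlation and adjusted p = 0.211 with an estimated correlation. Of 16 genes of antigen presentation, 3 rose and 2 fell, over all genes and adjusted over the list alone. ERAP1 (−0.74, SE 0.10) and HLA-E (−0.49, SE 0.10) fell and TAP2 (0.73, SE 0.14) and CD74 (0.57, SE 0.15) rose, with a camera Benjamini-Hochberg adjusted p = 0.964.

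Of 31 targets of p53, 11 fell and 1 rose, over all genes and adjusted over the list alone (median −0.31). Those that passed as lower numbered 6 without shCON replicate 1, 3 without shCON replicate 2 and 18 without shMAGED2 replicate 2. GDF15, SESN2 (−1.96, SE 0.13), CCNG1 (−0.81, SE 0.10) and the DNA repair factor XPC (−0.78, SE 0.11) fell, and DDB2 rose (0.49, SE 0.12; named after its value was seen). GDF15 also stands in the ATF4 list. For p53 targets camera gave a Benjamini-Hochberg adjusted p = 2.34e-05 with the preset correlation and adjusted p = 0.529 with an estimated correlation. Regulators of apoptosis were mixed, with 2 of 30 higher and 5 lower, over all genes and adjusted over the list alone. The pro-apoptotic BMF (−1.17, SE 0.16) and BBC3 (−1.42, SE 0.28) and the inhibitor XIAP (−0.64, SE 0.11) fell, and BIRC5, which also acts in mitosis, rose (1.22, SE 0.23). Camera with Benjamini-Hochberg adjustment gave 0.437. Of 12 genes of TRAIL and its death receptors, only the receptor TNFRSF10B passed, over all genes and adjusted over the list alone, falling from 274 ± 14.8 to 161 ± 19.7 CPM, and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.557).

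Because the series title names the AKT pathway, its genes were examined as a fixed list. The transcripts of the kinases AKT1 and AKT2 did not pass the test. AKT1 was at 159 ± 2.44 CPM in shCON and 161 ± 20.4 in shMAGED2 (log2 change 0.01, SE 0.12) and AKT2 at 129 ± 5.19 and 146 ± 13.8 (0.18, SE 0.11). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 0.945 and 0.262. AKT2 passed without shMAGED2 replicate 2 (0.28; edgeR, Benjamini-Hochberg adjusted p = 0.00082). The catalytic subunit PIK3CA was at 70.6 ± 1.58 and 66.4 ± 6.81 CPM and did not pass either (edgeR, Benjamini-Hochberg adjusted p = 0.614).

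Of the 39 genes of the PI3K-AKT core, 2 rose and 5 fell over all genes, and 1 rose and 2 fell when adjusted over the list alone. TRIB3, an ATF4 target whose protein binds AKT, fell from 96.2 ± 1.91 to 13.9 ± 2.45 CPM, and FOXO4 from 8.98 ± 1.28 to 4.82 ± 0.34. MAPKAP1, a subunit of mTORC2, rose from 220 ± 6.54 to 394 ± 9.73. The median was 0.04 and the mean −0.04 with a test direction of lower, so the signs differ, and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.831). Of 21 receptors and ligands upstream of AKT, 3 rose and 6 fell, over all genes and adjusted over the list alone: the growth factor FGF2 (−1.51, SE 0.09), the insulin receptor INSR (−1.40, SE 0.12) and PDGFRB (−1.12, SE 0.12) fell and the receptor kinase AXL rose (1.06, SE 0.10). Camera with Benjamini-Hochberg adjustment gave 0.177. Of 24 targets of FOXO transcription factors, which AKT restrains, 4 rose and 10 fell over all genes, and 4 rose and 11 fell when adjusted over the list alone. TXNIP rose, while INSR, KLHL24 (−1.02, SE 0.10) and the ubiquitin ligase FBXO32 (−0.93, SE 0.09) fell, and this list was not called either (camera, Benjamini-Hochberg adjusted p = 0.296). Fry, which does not compare a list with other genes, did call the FOXO targets (Benjamini-Hochberg adjusted p = 0.0129). It did not call the upstream genes (0.056) or the core (0.708).

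**Figure D3:**
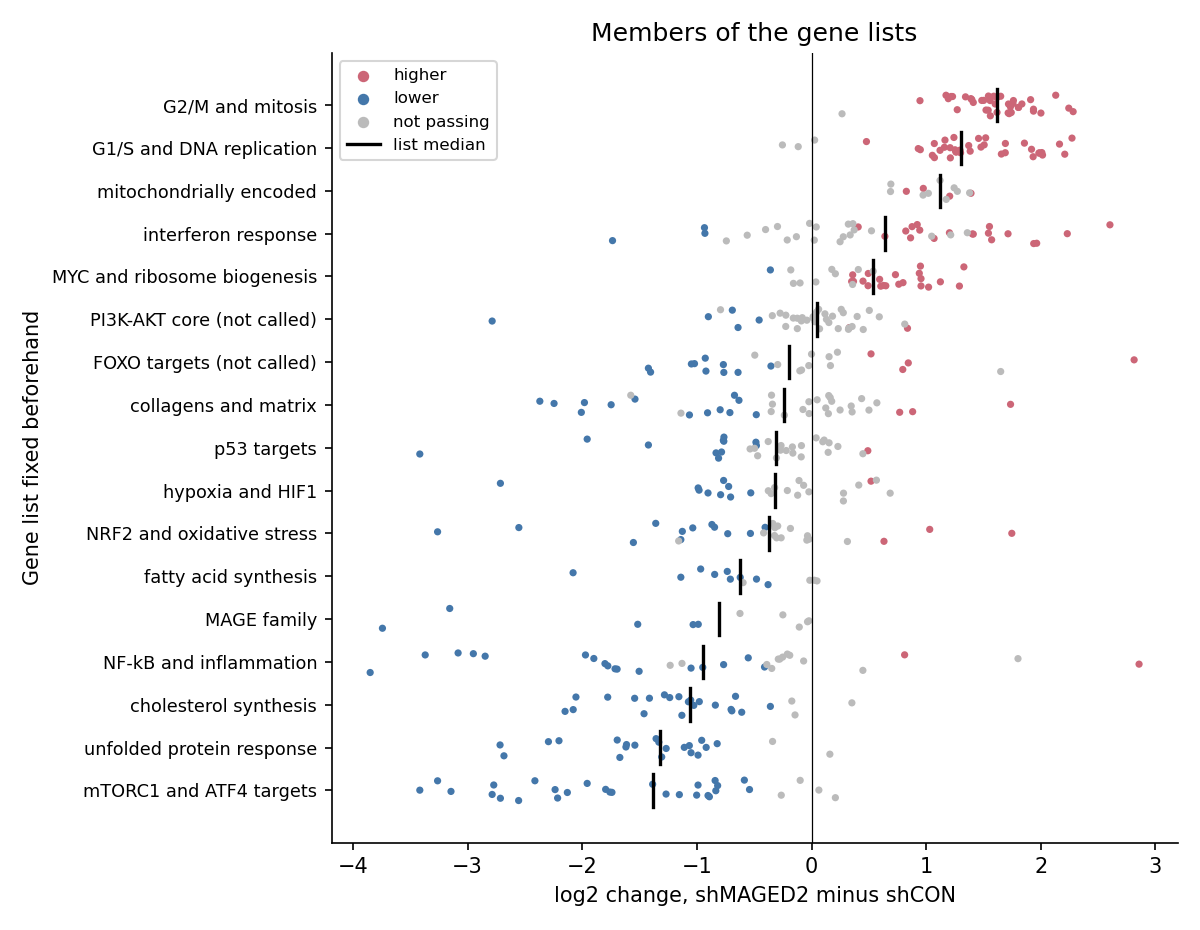
Log2 change (shMAGED2 minus shCON) of each measured member of the 15 called lists and of 2 lists that were not called, 1 point per gene, red where it rose, blue where it fell and grey where it did not pass; black bars are list medians. The medians run from −1.39 for mTORC1 and ATF4 targets to 1.62 for G2/M and mitosis, with the PI3K-AKT core at 0.04.

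Matrix genes moved in both directions. Of 37 collagens and other matrix genes, 13 fell and 3 rose over all genes, and 15 fell and 5 rose when adjusted over the list alone (median −0.24). Leaving out shCON replicate 1 or 2 left 6 and 7 lower, and leaving out shMAGED2 replicate 1 or 2 gave 6 and 8 higher. COL1A1 fell from 81.2 ± 0.28 to 27.9 ± 3.40 CPM, the basement membrane proteoglycan HSPG2 from 16.6 ± 0.02 to 4.20 ± 0.31 and the collagen chaperone SERPINH1 from 190 ± 2.35 to 90.8 ± 9.18, while the laminin chains LAMA4 and LAMB1 (named after their values were seen) rose, and the proteoglycan VCAN rose from 57.3 ± 1.04 to 191 ± 35.2. The camera call (preset correlation, Benjamini-Hochberg adjusted p = 0.0336) was lost with adjusted p = 0.634 with an estimated correlation. With 1 library left out the median ran from −0.13 without shCON replicate 2 to −0.36 without shMAGED2 replicate 1, and it was −0.075 with no count filter and −0.072 with GC and length trends removed. The call also ended without shCON replicate 2 (0.0752), without shMAGED2 replicate 2 (0.142), with limma-voom (0.0772), with the FPKM values (0.0976 and 0.09) and with GC and length trends removed (0.0676). Of 23 mesenchymal genes of the epithelial-mesenchymal transition, 6 fell and 0 rose over all genes, and 6 fell and 1 rose when adjusted over the list alone. FAP (−1.84, SE 0.10), LUM (−2.01, SE 0.30), DCN (−1.75, SE 0.26) and PRRX1 (−0.72, SE 0.12) fell. That list lay at the threshold (camera, Benjamini-Hochberg adjusted p = 0.05 after rounding, not called) and passed in 9 of 18 alternative fits, among them DESeq2 (0.044), library size alone (0.0319), no count filter (0.0302) and without shMAGED2 replicate 1 (0.00267). Of 29 proteases of invasion and their inhibitors, 8 fell and 3 rose over all genes, and 9 fell and 4 rose when adjusted over the list alone. The stromelysin MMP3 rose (1.70, SE 0.10), and ADAMTS5 (−1.49, SE 0.10) and the inhibitors TIMP4 (−1.32, SE 0.13) and TIMP3 (−3.17, SE 0.36) fell. Their median was 0.05 and their mean −0.23, with a camera direction of lower and a Benjamini-Hochberg adjusted p = 0.534.

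Of 29 integrins and focal adhesion genes, 8 rose and 2 fell, over all genes and adjusted over the list alone. ITGA2 (1.03, SE 0.11), ITGA3 (0.69, SE 0.09), paxillin PXN (0.85, SE 0.13) and ACTN4 (0.96, SE 0.15) rose, but the list was not called (camera, Benjamini-Hochberg adjusted p = 0.0741). It was called with limma-voom (0.0193), DESeq2 (0.044), no count filter (0.0444) and without shMAGED2 replicate 2 (0.0073). Of 21 targets of YAP and TEAD, 6 rose and 4 fell over all genes, and 8 rose and 4 fell when adjusted over the list alone, with AXL, AMOTL2 (0.72, SE 0.13) and NT5E (0.64, SE 0.12) higher and DLC1 (−0.68, SE 0.11) lower. Camera with Benjamini-Hochberg adjustment gave 0.214. Of 20 targets of TGF-beta and related signals, 5 rose and 4 fell, over all genes and adjusted over the list alone, with ID1 (2.65, SE 0.14) higher and SKIL (−1.23, SE 0.10), TGIF1 (−0.79, SE 0.09) and TGFBI (−0.86, SE 0.12) lower (camera, Benjamini-Hochberg adjusted p = 0.373). Among 11 Wnt targets, 2 rose and 0 fell, over all genes and adjusted over the list alone: the Wnt inhibitor RNF43 from 4.23 ± 0.05 to 23.3 ± 1.89 CPM and MYC from 55.6 ± 0.69 to 136 ± 37.4. The Wnt list was not called (camera, Benjamini-Hochberg adjusted p = 0.0751), except without shCON replicate 1 (0.0365). RNF43 overlaps SUPT4H1 on the same strand, which leaves its reads uncertain. Of 17 genes of Notch signalling and stemness, 1 rose and 4 fell over all genes, and 4 rose and 5 fell when adjusted over the list alone. Nestin (NES) rose from 5.19 ± 0.66 to 19.0 ± 0.39 CPM, and HEY1 (−1.65, SE 0.21), NOTCH3 (−1.94, SE 0.31) and OLIG2 (−1.45, SE 0.27) fell; camera with Benjamini-Hochberg adjustment gave 0.437.

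Of 10 measured MAGE genes, 5 fell and 0 rose, over all genes and adjusted over the list alone (median −0.81), and 3 fell without shCON replicate 1 or without shCON replicate 2. Besides the targeted MAGED2, these were MAGED4 (30.1 ± 1.26 to 14.7 ± 0.66 CPM), MAGED4B (29.2 ± 0.36 to 14.7 ± 0.79), MAGEL2 (2.59 ± 0.14 to 0.20 ± 0.24) and NDN, the latter named after its value was seen. MAGED4 and MAGED4B are near-identical copies and their reads cannot be assigned with certainty. Camera on the MAGE genes gave a Benjamini-Hochberg adjusted p = 3.29e-05 with the preset correlation and adjusted p = 0.211 with an estimated correlation, and MAGED2 itself is part of this list.

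The 13 mitochondrially encoded genes were higher in shMAGED2, mainly in 1 library. Their share of the counts was 3.92% and 3.90% in shCON and 10.08% and 4.87% in shMAGED2. Over all genes 4 rose and 0 fell, and 10 rose when adjusted over the list alone (median 1.12). In edgeR 0 passed without shCON replicate 1 or 2, while 12 and 13 rose without shMAGED2 replicate 1 and 2. MT-CYB was at 1589 ± 47.6 CPM in shCON and 4166 ± 2101 in shMAGED2 (log2 change 1.39, SE 0.33), MT-ND3 at 94.5 ± 2.57 and 168 ± 44.0, MT-ND6 at 490 ± 14.7 and 963 ± 390 and MT-ATP6 at 3785 ± 13.7 and 8723 ± 4369. Camera gave a Benjamini-Hochberg adjusted p = 0.00296 with the preset correlation and adjusted p = 0.70 with an estimated correlation. The median was 0.48 without shMAGED2 replicate 1 and 1.6 without shMAGED2 replicate 2, and the call ended when GC and length trends were removed (median 0.98, adjusted p = 0.103 by camera).

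Nuclear genes of oxidative phosphorylation were not called (camera, Benjamini-Hochberg adjusted p = 0.713). Of 43, 2 rose over all genes (CYC1, from 113 ± 7.14 to 155 ± 0.08 CPM, and ATP5MC1, from 23.6 ± 5.02 to 44.5 ± 12.04), 0 rose when adjusted over the list alone, and 0 fell. Their median was 0.19 without shMAGED2 replicate 1 and −0.22 without shMAGED2 replicate 2, called in opposite directions (camera, Benjamini-Hochberg adjusted p = 0.008 and 0.0164). Of 55 ribosomal proteins, 4 rose (RPL35 by 0.98, SE 0.10, and RPS24, RPS15 and RPL6) and 1 fell over all genes (RPL37, named after its value was seen), and 3 rose and 0 fell when adjusted over the list alone. Their median was −0.05 and their mean −0.02 against a camera direction of higher (Benjamini-Hochberg adjusted p = 0.897), and they too turned direction with the library left out, at 0.14 without shMAGED2 replicate 1 and −0.20 without shMAGED2 replicate 2 (adjusted p = 0.0385 and 0.00026 by camera).

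Several further lists held members that passed without a call for the list. Of 15 heat shock genes, 4 rose and 3 fell over all genes, and 6 rose and 3 fell when adjusted over the list alone. HSPB8 (1.12, SE 0.12), HSPA4L (1.22, SE 0.16) and HSP90AA1 (0.62, SE 0.09) rose and HSPA1B (−1.28, SE 0.09) fell, with a camera Benjamini-Hochberg adjusted p = 0.534. Of 33 immediate early and MAPK response genes, 8 rose and 5 fell over all genes, and 11 rose and 7 fell when adjusted over the list alone, with KLF6 (0.80, SE 0.09), FOSL2 (0.74, SE 0.09) and SPRY2 (0.78, SE 0.09) higher and the stress factor ATF3 (−2.56, SE 0.20) lower (camera, Benjamini-Hochberg adjusted p = 0.557). Of 35 genes of autophagy and lysosomes, 8 fell and 2 rose, over all genes and adjusted over the list alone. The proton pump subunit ATP6V0D2 (−1.57, SE 0.12), GABARAPL1 (−1.25, SE 0.11), the protease CTSF (−1.40, SE 0.14) and WIPI1 (−1.35, SE 0.14) fell, and CTSD and ATP6V0D1, named after their values were seen, rose; camera with Benjamini-Hochberg adjustment gave 0.153. Of 21 genes of cAMP and protein kinase A, 3 rose and 2 fell, over all genes and adjusted over the list alone: PDE4B (1.38, SE 0.15), ADCY3 (0.75, SE 0.11) and PRKACA (0.64, SE 0.11) rose and PRKACB (−0.76, SE 0.14) fell (camera, Benjamini-Hochberg adjusted p = 0.579).

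Of 20 palmitoyltransferases, 2 rose and 2 fell over all genes, and 1 rose and 2 fell when adjusted over the list alone. ZDHHC12 (1.18, SE 0.12) and ZDHHC16 (0.73, SE 0.20) rose and ZDHHC24 (−0.58, SE 0.12) and ZDHHC1 (−0.80, SE 0.17) fell, with a camera Benjamini-Hochberg adjusted p = 0.437. Of 13 genes of the RNA interference machinery, only DROSHA passed, over all genes and adjusted over the list alone, rising from 58.4 ± 4.71 to 101 ± 20.2 CPM (camera on the list, Benjamini-Hochberg adjusted p = 0.449).

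Few markers of astrocytes and of other cell types were measured. Camera with the preset correlation called none of these lists, whereas fry called the astrocyte list (Benjamini-Hochberg adjusted p = 0.0127). Of 8 astrocyte markers, 2 fell and 0 rose, over all genes and adjusted over the list alone: APOE from 14.02 ± 0.59 to 1.59 ± 0.20 CPM and glutamine synthetase GLUL from 250 ± 5.92 to 164 ± 10.1 (camera, Benjamini-Hochberg adjusted p = 0.111). Of 8 neuronal markers, TUBB3 rose (0.88, SE 0.11) and MAP2 fell (−1.97, SE 0.28), the same counts when adjusted over the list alone; their median was 0.19 and their mean −0.02 (camera, Benjamini-Hochberg adjusted p = 0.962). Of 4 oligodendrocyte markers, CSPG4 rose (0.74, SE 0.09) and OLIG2 fell, over all genes and adjusted over the list alone. Of 5 immune markers none passed over all genes or adjusted over the list alone, with CD4 at 0.47 ± 0.01 and 0.80 ± 0.74 CPM; their median was 0.09 and their mean −0.08 (camera, Benjamini-Hochberg adjusted p = 0.962). Of 4 endothelial markers, KDR fell over all genes (−0.68, SE 0.18), and 2 fell when adjusted over the list alone. Of 7 epithelial markers, ESRP1 fell over all genes and 0 when adjusted over the list alone, with 60 counts over shCON and 3 over shMAGED2 (ratio 20.6, 95% counting interval 6.72 to 103; camera on the list, Benjamini-Hochberg adjusted p = 0.538). The oligodendrocyte and endothelial lists had too few measured members for a list test.

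Over the 43 lists tested, camera with the preset correlation called 15, of which 5 were higher and 10 lower. With an estimated correlation camera called 0 after Benjamini-Hochberg adjustment, and 10 lists had an unadjusted p under 0.05. This form of the test also rests on the 2 residual degrees of freedom, which limits how small its p can be. For G1/S genes the estimated correlation was −0.00952, under the preset 0.01, yet the camera adjusted p went from 2e-45 to 0.11. The lost calls therefore cannot show whether correlation between genes produced the calls. Fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, called 18 lists, and 38 for change in either direction. The 2 tests did not call the same lists. Fry did not call mitochondrially encoded genes (Benjamini-Hochberg adjusted p = 0.304) or collagens and matrix genes (0.0509). Only fry called FOXO targets (0.0129), Wnt targets (0.0125), replication-dependent histones (0.028), the RNA interference machinery (0.00878) and astrocyte markers (0.0127).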

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

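Of the tests below, removal of mitochondrially encoded genes, removal of GC and length trends and the restriction to annotated genes were chosen after seeing the data. MAGED2 stayed lower and past the threshold in each of the 18 alternatives, from −3.03 to −3.31. No gene called in the reported edgeR fit was called in the opposite direction in any alternative, and the median change of all genes stayed within 0.1. The number of genes changed at least 2-fold was 751 with limma-trend on log2(FPKM + 1), and the genes higher in shMAGED2 numbered 1236 on log2(FPKM + 0.1). Both fits changed the test, the values and the filter together, with fewer genes (12554) tested. The pseudocount of 1 also shrinks changes of low genes by construction, and these reasons were not separated. Leaving out 1 library moved the genes changed to between 1100 and 7447, the genes higher to between 567 and 3725 and the genes lower to between 533 and 3722. The low ends came without shCON replicate 1 (1100) or 2 (1272) and the high ends without shMAGED2 replicate 1 (6565) or 2 (7447), where the lone library was assumed to vary like the other pair. The spread within the remaining pair set these counts by construction, and the shMAGED2 pair lay further apart (chi-square per degree of freedom 95.65) than the shCON pair (7.61). Fixed gene lists called by camera numbered 13 to 19 in these fits, but 0 with the correlation estimated. Nuclear oxidative phosphorylation genes turned from a median of 0.188 without shMAGED2 replicate 1 to −0.22 without shMAGED2 replicate 2, and ribosomal proteins from 0.142 to −0.203, and the cause was not tested. Collagen and matrix genes lost their call in 6 of these 18 fits, hypoxia genes in both FPKM fits and mitochondrially encoded genes once GC and length trends were removed (adjusted p = 0.103 by camera with Benjamini-Hochberg adjustment). Lists called only in some alternatives were the mesenchymal genes, replication-dependent histones, integrins, glycolysis, Wnt targets, oxidative phosphorylation and ribosomal proteins. Without shCON replicate 1 or 2, 48 of 169 genes besides MAGED2 picked by the naming rule missed the threshold in each case. Of those reported here, the 4 mitochondrially encoded genes, MAGEL2, FOXO4, HSP90AA1, HK1, PFKP, MXI1, CYC1, CDKN1A, XIAP, PRRX1, ITGA3, DLC1, AMOTL2, NT5E, OLIG2, RPS24, RPS15, RPL6, TAP2, HLA-E, CD74, FOSL2, SPRY2, FTH1, ADCY3, PRKACA, PRKACB, 4 histone genes, ZDHHC24, ZDHHC1, ZDHHC16, DROSHA, GLUL, CSPG4, KDR and ESRP1 missed it in both. BIRC5, DCN, PXN, ERAP1 and KLF6 missed it without shCON replicate 1 alone, and ATP5MC1, XPC, BBC3 and TNFRSF10B without shCON replicate 2 alone. With GC and length trends removed, 1981 genes were higher and 1520 lower (56.6% higher, against 51.4%), while 45.2% were higher with upper-quartile factors (1655 and 2008), 44.9% with library size alone (1508 and 1853) and 46% and 46.3% with log2(FPKM + 1) and log2(FPKM + 0.1). Deviations of same-numbered libraries from their group means were not correlated over genes (−0.017). This cannot show whether they shared a culture or day, which the labels do not say. A replicate block gave 3336 genes (1706 higher, 1630 lower), with 86.2% of the calls kept, added the mesenchymal list (camera, Benjamini-Hochberg adjusted p = 0.0488) and ended the calls of RPL6, HIST2H2AC, HIST1H3E and KDR. In simulated counts at this depth, with 2 libraries per group and 67 of 15293 genes changed 1.5-fold, 28.4% of those changes were recovered. Far more genes were called in the data than were changed there, so the share of small changes missed in the data is not known.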

Other observations

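The lists in this paragraph, and the tests of them, were chosen only after the results were seen. Their p-values were adjusted over these lists alone, apart from the 43 lists tested before. The adjusted p-values here therefore cannot be set beside those of the earlier lists. Genes of DNA repair and chromosome structure that none of the earlier lists held rose in shMAGED2. Of 30 genes of the Fanconi anaemia pathway and homologous recombination, 19 rose and 0 fell (median log2 change 0.73), among them FANCD2, from 16.6 ± 1.08 to 53.2 ± 0.20 CPM (SD, n = 2), the nuclease EXO1, from 10.6 ± 0.05 to 37.9 ± 2.73, and BRCA1, from 36.3 ± 0.22 to 96.1 ± 5.86. Limma's camera with Benjamini-Hochberg adjustment gave 1.42e-13 for this list, and adjusted p = 0.0784 with an estimated correlation. Of 21 condensin and cohesin genes, 12 rose and 1 fell (median 0.62; camera, Benjamini-Hochberg adjusted p = 8.97e-12, and adjusted p = 0.0784 with an estimated correlation). NCAPG (1.69, SE 0.10) and SMC2 (1.28, SE 0.09) rose, and the cohesin acetyltransferase ESCO1 fell by 0.43 on the log2 scale. Of 23 genes of transport from the endoplasmic reticulum to the Golgi, 14 fell and 0 rose (median −0.46), among them the tether USO1 (−0.84, SE 0.09) and MIA2 (−1.28, SE 0.14), with a camera Benjamini-Hochberg adjusted p = 1.83e-05 and adjusted p = 0.0784 with an estimated correlation. Cytosolic aminoacyl-tRNA synthetases moved both ways, with 9 of 20 lower and 3 higher (median −0.26). WARS (−1.74, SE 0.13) and GARS (−1.15, SE 0.10) fell, while FARSB, HARS and KARS rose (camera, Benjamini-Hochberg adjusted p = 0.00402, and adjusted p = 0.108 with an estimated correlation). Of 17 mitochondrial synthetases, 6 rose and 0 fell, and that list did not pass (camera, Benjamini-Hochberg adjusted p = 0.175). Of 11 BEX and TCEAL genes, neighbours on the X chromosome, 5 fell and 0 rose (median −0.40; camera, Benjamini-Hochberg adjusted p = 0.000373, and adjusted p = 0.108 with an estimated correlation), with BEX2 from 38.4 ± 0.63 to 8.43 ± 2.32 CPM.

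Some genes were counted in 1 group only. Among genes called higher by edgeR, 25 had 0 counts in both shCON libraries, 12 of them with an Ensembl identifier. The receptor gene IL22RA1 (chromosome 1, 24119771 to 24143121) had 128 and 109 counts in shMAGED2 and was at least 76.7-fold higher, taking 3 counts over the shCON group as the limit. Among genes called lower, 38 had 0 counts in both shMAGED2 libraries, 23 of them with an identifier. The synaptotagmin gene SYT7 (chromosome 11, 61515313 to 61581148), with 67 and 51 counts in shCON, was at least 40.5-fold lower, and LRMDA, with 51 and 44, at least 32.6-fold lower. Of the gene models without an identifier, 14.8% of 1977 changed, and of the identified genes 25.2% of 13316, a difference that was not tested.

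The explanations weighed from here on, and what each predicts, were written after the results were seen; the fit without shMAGED2 replicate 1 and the filter at 5 CPM had been set before, and the removal of GC and length trends had not. Cell cycle genes were higher and genes of the unfolded protein response lower in shMAGED2. The library with the most mitochondrial reads does not account for this, since without it the G2/M median was 1.584 and the unfolded protein median −1.289, both still called by camera at the preset correlation; with all libraries and an estimated correlation neither was called (Benjamini-Hochberg adjusted p = 0.11 for each). GC content and length do not account for it either, with medians of 1.634 and −1.322 once those trends were removed. A culture difference stays open: the glucose-responsive genes TXNIP and ARRDC4, a list written after the results were seen, had a median change of 2.404, which is what control cultures short of glucose at harvest could give, but no label states density or medium age, and a knockdown effect could give it too. The knockdown itself, other targets of the hairpin and culture state cannot be told apart in this design.

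Mitochondrially encoded genes were higher in shMAGED2 with a median of 1.12, and 0.48 without shMAGED2 replicate 1, so most of the difference may come from that library. With GC and length trends removed the median was 0.985, but the call ended (camera, Benjamini-Hochberg adjusted p = 0.103). GC or length bias and a change in these transcripts cannot be told apart here. No biological explanation was tested for the difference between the 2 shMAGED2 libraries.

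Interferon-stimulated genes were higher in shMAGED2 with a median of 0.64. Among genes of at least 5 CPM in 2 libraries the list kept its call, with a lower median of 0.369 (camera, Benjamini-Hochberg adjusted p = 0.00106). A gene can pass that filter on its 2 shMAGED2 libraries alone. Counts near the detection limit in shCON are therefore not excluded as a part of the difference. The full list was not called with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.211). Removal of GC and length trends left the list median at 0.624 (camera, Benjamini-Hochberg adjusted p = 6.63e-05). A hypothesis that remains is a response to hairpin RNA or vector that differed between the hairpins, or an effect of MAGED2 loss, and neither was tested.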
